A study of Mus musculus and Homo sapiens with 39 samples.

How the data were processed

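The series holds 25 RNA-seq libraries of primary mouse HSCs and 14 chromatin immunoprecipitation or input samples of mouse and human HSCs. Per the labels, mouse HSCs (C57BL/6) were transduced with lentiviral hairpins at a multiplicity of infection of 30 for 36 h and selected with puromycin at 5 µg/ml for 48 h, and stranded total RNA was sequenced. The protocol names SHC-002 as the control for Ets and Gata hairpins and SHC-202 for Irf hairpins. The deposited RNA values are a signal per gene and library, read counts that the authors divided by a DESeq size factor for each library. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.1a, RSEM 1.3.0 and the build GRCm38/mm10. The step between neighbouring values gave the value of 1 read in each library, and at least 99.995% of values were whole numbers of reads within 0.05 of a read. In 1 Gata4/6 library this step was too close to 1 for a shared check, so its values were tested against the step. Recovered reads ran from 12853227 to 24249704 per library, and the 10 most abundant genes held 7.08% to 12.1% of the values.

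Of 20232 genes, 662 were at 0 in all libraries, and 13965 with a value of at least 10 in at least 2 libraries were tested. Log2 of the value plus 1 was fitted with limma 3.58.1 in R 4.3.3 (trend, robust), with a mean for each of the 13 groups, so that the spread was estimated over all groups with 12 residual degrees of freedom and the single SHC002 library could be compared. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Folds are ratios of group means and log2 changes are those of the fit. Replicates correlated across genes at r = 0.989 to 0.995, and the 12 replicate pairs all differed by more than counting error, with a median absolute log2 difference of 0.0823 to 0.142. Folds of 2 or more were found again in 98.5% to 100% of genes and folds of 1.5 in 77.6% (2 libraries against 1) to 94% (2 against 2) when tested on simulated data, in which 9 to 16 unchanged genes and 0 to 2 of 22 lists were called.

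Gene lists were written before the data were examined. Each list with at least 5 tested members was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 198 tests (22 lists in 9 comparisons), and again with an estimated correlation. The preset test called 135 of the 198, the test with an estimated correlation 51, and limma's fry 166. The preset test is laxer, so called lists carry both adjusted p-values where the second exceeds 0.05, except against the other control hairpin. Members were also adjusted over the list alone. Some families hold near-identical paralogs (such as Serpina3, Gzm and Mcpt), for which counting could split reads between genes.

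The genes named in the text follow a rule fixed in advance. Targeted genes came first. Among genes past adjusted p 0.05 with a mean of at least 50 in the compared libraries, no overlap between the groups and no predicted or clone name, the 8 largest rises and 8 largest falls of each pair knockdown and the 4 and 4 of each single knockdown could be named. Up to 4 members of a list with the largest change could be named in pairs and up to 2 in singles. Acta2, Col1a1, Col1a2, Timp1, Lox, Lrat and Pparg could be named in every comparison. Genes with a total of 3 or fewer reads in a compared group were left out.

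The deposited peak lists give only the start and end of each called peak in bp. Per the file headers they were called with HOMER against input in histone style, 1 library per list, at a fold over input of 4, a Poisson p of 1.00e-04 and a local fold of 4. The submitters' processing notes name Bowtie2 and the builds mm10 and hg38. Tags per list ran from 7.02 in mouse H3K4me2 at 1 week to 23.1 in human H3K4me2 source 2, in units of 1e6 tags. Overlaps of at least 1 bp were counted with bedtools 2.31.1 in Python 3.11.15. Intervals are 95% exact binomial intervals from SciPy 1.17.1, and the other list moved by 1 Mb gave the background. Genes were scored by a peak within 2000 bp of the gene interval, which replaced the planned promoters because the reference holds no strand. Figures were drawn with matplotlib 3.10.9.

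Alternatives tried were a pseudocount of 5, no filter, a fit of only the groups compared, same-dose controls pooled, all 7 controls pooled, quantile normalisation, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, each replicate left out, and other overlap rules. Left out were motifs, since no genome was given, peak scores, since the files hold none, and peaks on human sex chromosomes.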

Results

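Hepatic stellate cells (HSCs) are the vitamin A-storing pericytes of the liver, and in fibrosis they turn into contractile, collagen-secreting cells. Primary mouse HSCs were transduced with lentiviral short hairpins against 6 transcription factors that mark the stellate lineage, and their total RNA was sequenced. The series title states the question, whether such factors hold activation back. Ets1, Ets2, Gata4, Gata6, Irf1 and Irf2 were targeted singly, each with 1 named hairpin (the labels give 2 different numbers for that of Gata4), and in the pairs Ets1/2, Gata4/6 and Irf1/2. Each knockdown had 2 libraries. The control hairpin SHC002 had 1 library as a single vector and 2 as a double vector (SHC002x2), and the control hairpin SHC202 had 2 of each (SHC202 and SHC202x2). Each knockdown was compared at its own vector dose with the protocol's control, SHC002 for Ets and Gata hairpins and SHC202 for Irf hairpins. The 25 libraries held 12853227 to 24249704 recovered reads each, and 13965 genes were tested. The labels do not say that replicates are separate cultures, so the p-values measure the spread between these libraries and not between animals. With 1 hairpin per gene, an effect of the targeted gene could not be told from an effect of that hairpin.

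Chromatin was profiled by chromatin immunoprecipitation and sequencing of H3K4me2, a mark of promoters and enhancers, and H3K27ac, a mark of active ones. Mouse HSCs were taken quiescent, activated in injured liver, and after 1 week and 1 month of recovery, with 1 library per mark and stage and no replicates. The file headers of the 1 week lists name a directory of 10 days, so their time is uncertain. Human HSCs from 2 sources were profiled for the same marks. Only called peaks were deposited, so the values for chromatin are peak numbers, lengths and overlaps.

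The targeted gene was lower than in the matched control in each single knockdown. Ets1 fell 2.33-fold in the Ets1 knockdown, to a normalised read count of 1166 ± 69.5 (SD, n = 2) from 2714 in the single SHC002 library (limma adjusted p = 1.48e-13). Ets2 fell 3.01-fold in the Ets2 knockdown, to 701 ± 1.31 from 2112 (limma adjusted p = 5.27e-16). Gata4 fell 1.79-fold, to 729 ± 41.2 from 1308 (limma adjusted p = 2.69e-09), and Gata6 fell 1.36-fold, to 437 ± 6.29 from 595 (limma adjusted p = 0.0012). Irf1 fell 1.92-fold, to 480 ± 26.5 from 920 ± 8.22 in SHC202 (limma adjusted p = 6.31e-10). Irf2 fell 3.14-fold, to 323 ± 27.2 from 1014 ± 25.4 (limma adjusted p = 6.63e-16). Against the other control hairpin, Ets1 was lower in its own knockdown by less (log2 −0.26 in place of −1.22), as was Irf1 (log2 −0.38 in place of −0.94), and Gata6 was no lower (log2 0.18, limma adjusted p = 0.0777). Gata6 was also no lower than in the 9 groups with no Gata hairpin other than SHC002x2 (log2 −0.14, limma adjusted p = 0.0823).

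The pairs lowered fewer of their targets. In the Ets1/2 libraries Ets2 fell 2.54-fold, to 641 ± 28.8 from 1626 ± 52.9 in SHC002x2, while Ets1 stood at 2033 ± 38.9 against 2191 ± 1.41 and did not pass the test (limma adjusted p = 0.116). In the Gata4/6 libraries neither target was lower than in SHC002x2. Gata4 stood at 744 ± 1.77 against 788 ± 21.0 (limma adjusted p = 0.299), and Gata6 stood at 418 ± 10.6 against 363 ± 10.7 (limma adjusted p = 0.0403, a call lost under 4 other methods and with any library left out). Irf1 and Irf2 both fell in the Irf1/2 libraries, Irf1 2.02-fold to 372 ± 8.54 from 752 ± 49 in SHC202x2 and Irf2 1.60-fold to 478 ± 10.0 from 764 ± 66.9. Pairs were also set against the mean of the 9 groups with no hairpin of their family, SHC002x2 left out. Gata4 was lower in Gata4/6 (log2 −0.57, limma adjusted p = 1.63e-10). Gata6 was lower by less (log2 −0.20, limma adjusted p = 0.00952) but not against SHC202x2 (log2 0.01). Ets1 was unchanged in Ets1/2 (log2 0.02, limma adjusted p = 0.729). The names Ets1/2 and Gata6 knockdown below are labels, not proof of a loss of Ets1 or Gata6.

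**Figure D1:**
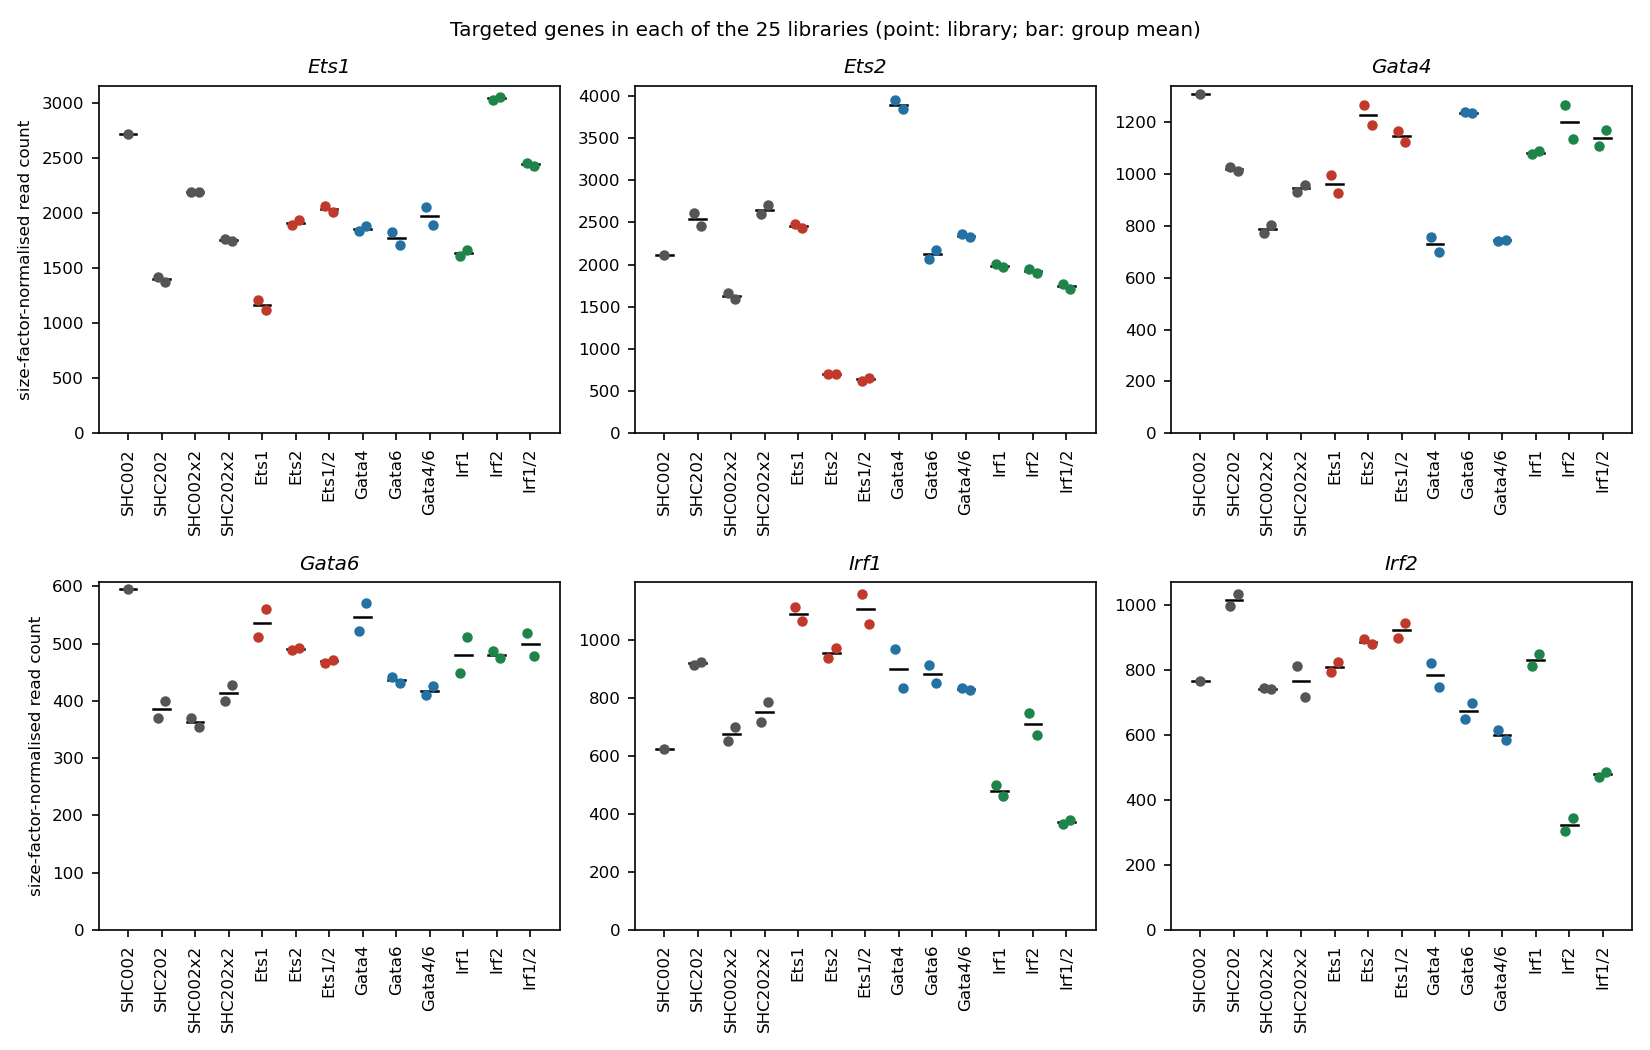
Size-factor-normalised read counts (vertical axes, from 0) of the 6 targeted genes in the 13 groups of RNA libraries. Each point is a library and each bar a group mean, and Ets2 fell to 641 in Ets1/2 while Ets1 stayed at 2033.

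Libraries with the 2 control hairpins differed. Collagens, proliferation genes and interferon-stimulated genes were all lower with SHC002 than with SHC202, as single and as double vectors. In SHC002x2 against SHC202x2, 16 of 17 tested collagen genes were lower (mean log2 −1.13), as were 34 of 35 cell cycle genes (mean log2 −0.83) and 28 of 32 interferon-stimulated genes (mean log2 −0.95). Hepatocyte markers were lower too, at 11 of 12 genes (mean log2 −1.77). For the single vectors the means were −0.93 for collagens, −1.06 for cell cycle genes and −0.94 for interferon-stimulated genes. The controls differed in 4292 genes as single vectors and in 4098 as double vectors. Of these, 835 were higher with SHC002 at both doses and 1268 were lower at both, where independent lists would share 256 and 378, and 173 turned. Every knockdown value therefore depends on its control, and the mean against the other control hairpin of the same dose is given for each list. Against it, 40 of the 135 list calls changed the sign of their mean and 74 kept their sign and passed again.

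**Figure D2:**
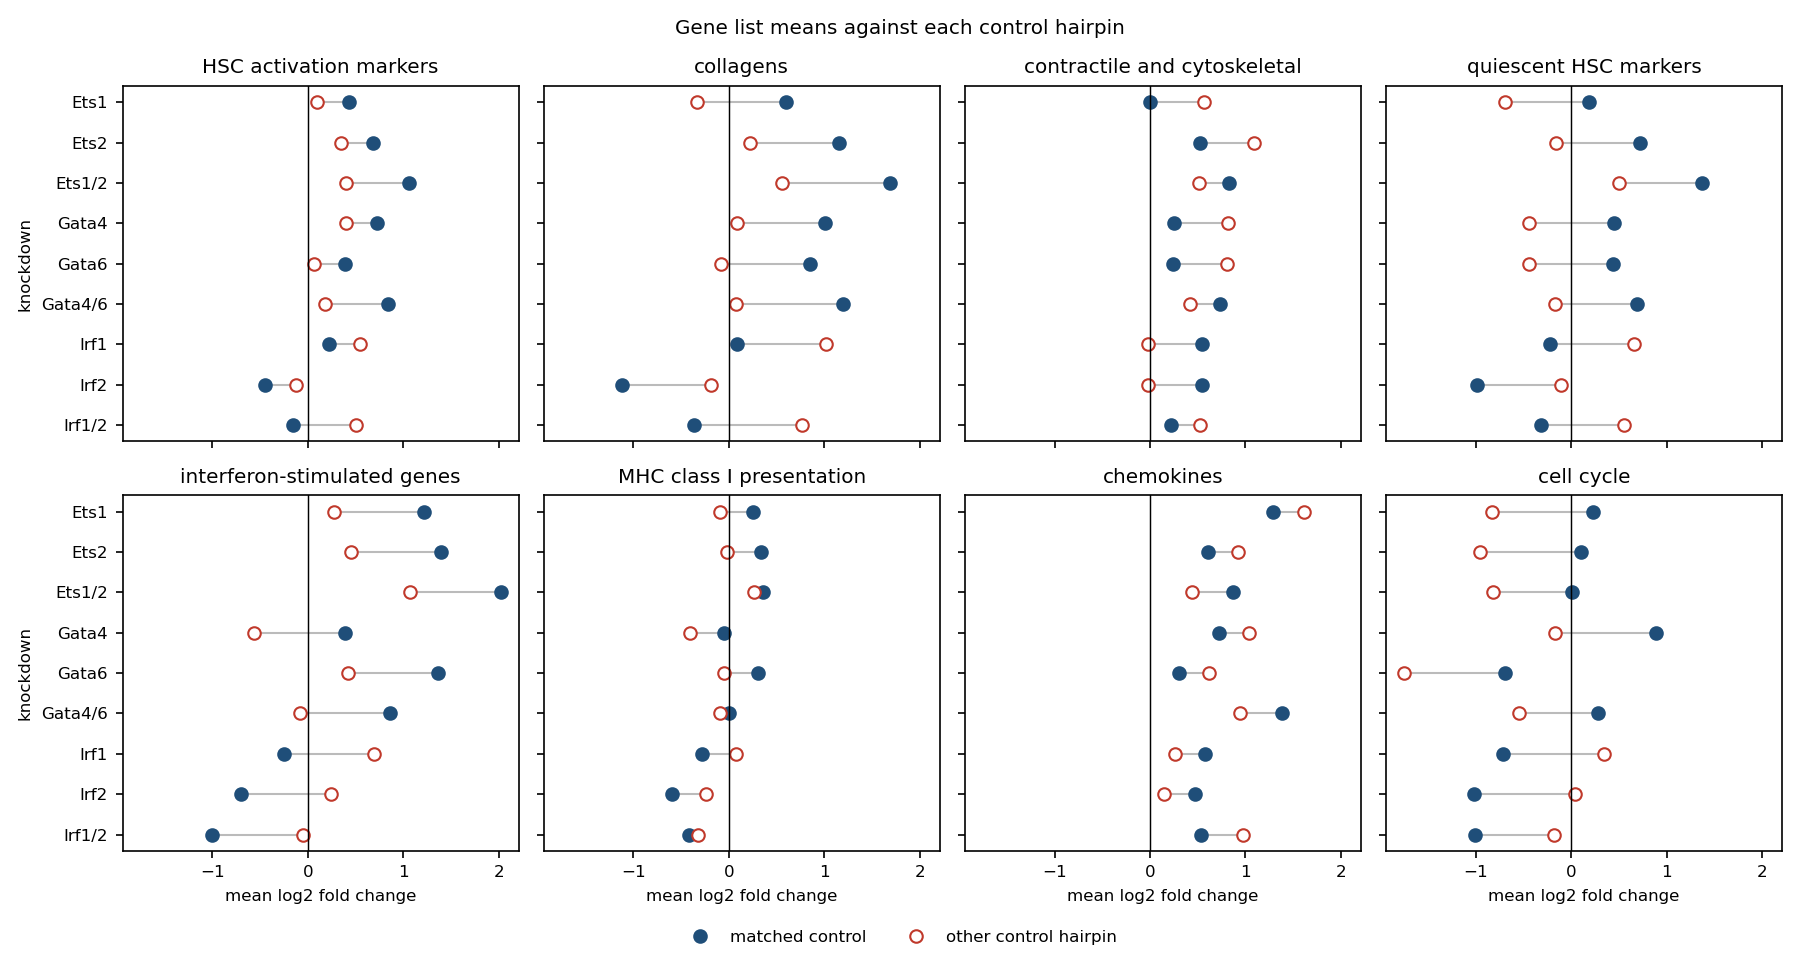
Mean log2 change (horizontal axes) of 8 gene lists in the 9 knockdowns, against the matched control (filled points) and the other control hairpin (open points). Collagens in Ets1/2 were at 1.69 and 0.56, and interferon-stimulated genes in Irf1/2 at −0.998 and −0.05.

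The Ets1/2 comparison asked, by its label, whether HSCs with hairpins against the Ets pair gain activation genes, though of the pair only Ets2 was lower. Collagens, matrix proteins, the contractile apparatus and activation markers rose in these libraries, and so did interferon-stimulated genes. Markers of quiescent HSCs rose as well. Lipid droplet genes fell. Among 6637 genes past limma adjusted p 0.05, 3413 rose and 3224 fell, and 1535 changed by at least 2-fold.

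All 17 tested collagen genes rose in Ets1/2, and 17 did so when adjusted over the list alone, with a mean log2 change of 1.69 ± 0.81 (SD over genes, camera adjusted p = 2.32e-16) and 0.56 against SHC202x2. Col3a1, a fibrillar collagen of scar tissue, rose 9.75-fold to 29767 ± 765 from 3053 ± 192 (n = 2 each). The type I collagen chains followed, Col1a2 at 6.46-fold (27988 ± 316 against 4333 ± 153) and Col1a1 at 3.34-fold (35538 ± 2850 against 10650 ± 586). Of 30 matrix glycoprotein and remodelling genes, 26 rose and 2 fell (28 changed when adjusted over the list alone), with a mean of 1.08 (camera adjusted p = 1.32e-15) and 0.30 against SHC202x2. Lum, a proteoglycan that binds collagen fibrils, rose 13.8-fold, and Lox, which cross-links collagen, rose 3.17-fold to 6019 ± 192. Mmp13, a collagenase, went the other way and fell 5.66-fold, to 5656 ± 440 from 32032 ± 15.7. Contractile genes rose at 13 of 17 with 1 fall (14 changed when adjusted over the list alone) and a mean of 0.82 (camera adjusted p = 2.27e-08, adjusted p = 0.0939 with an estimated correlation), or 0.52 against SHC202x2. Cnn1, a calponin of smooth muscle, rose 4.28-fold, and Acta2, the smooth muscle actin of activated HSCs, rose 2.11-fold to 37326 ± 3030 from 17684 ± 832.

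Activation markers rose at 22 of 25 genes in Ets1/2, with 2 falls and 1 gene not past the test (24 changed when adjusted over the list alone). Their mean was 1.06 (camera adjusted p = 2.22e-14), or 0.40 against SHC202x2. Postn, a matricellular protein, rose 3.89-fold, and Timp1, an inhibitor of matrix proteases, rose 1.91-fold to 5956 ± 389 from 3127 ± 277. Of 27 quiescent HSC markers, 21 rose and 3 fell (24 changed when adjusted over the list alone), with a mean of 1.37 (camera adjusted p = 1.03e-08) and 0.50 against SHC202x2. Lrat, which makes the retinyl esters HSCs store, rose 3.32-fold to 696 ± 22.7 from 210 ± 51.7. Pparg, a nuclear receptor of fat-storing cells, fell 1.62-fold.

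Interferon genes rose as a group. In Ets1/2, 31 of 32 interferon-stimulated genes rose (31 when adjusted over the list alone), with a mean of 2.02 (camera adjusted p = 5.24e-22, adjusted p = 0.0556 with an estimated correlation), or 1.07 against SHC202x2. Mx1, an antiviral GTPase, rose 27.7-fold to 129 ± 20.9 from 4.66 ± 0.11, and Ifit3 rose 15.9-fold to 1526 ± 65.5 from 95.8 ± 7.40. Interferon-gamma-induced GTPases and their partners rose at 9 of 12 (9 when adjusted over the list alone, camera adjusted p = 9.19e-08), with a mean of 1.83, or 0.92 against SHC202x2, and Iigp1 rose 17.9-fold. Chemokines and inflammatory mediators rose at 17 of 24 with 2 falls (19 changed when adjusted over the list alone), with a mean of 0.87 (camera adjusted p = 2.68e-05, adjusted p = 0.172 with an estimated correlation) and 0.44 against SHC202x2.

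Lipid droplet genes fell at 8 of 17 in Ets1/2 and rose at 3 (11 changed when adjusted over the list alone), with a mean of −0.31 (camera adjusted p = 0.00804) against either control. The fatty acid transporter Cd36 fell 3.44-fold, to 15360 ± 1450 from 52819 ± 3240, the fatty acid carrier Fabp4 fell 5.25-fold, and Hilpda, a lipid droplet protein induced by low oxygen, fell 7.05-fold to 753 ± 22.8 from 5305 ± 115. Dio2, a deiodinase that activates thyroid hormone, fell 19.5-fold to 111 ± 0.56 from 2171 ± 283, and Bex1 fell to 22.8 ± 4.38 from 468 ± 16.7. Targets of p53 rose at 12 of 16 with 2 falls (14 changed when adjusted over the list alone, camera adjusted p = 0.00846), with a mean of 0.31, or 0.34 against SHC202x2. Cell cycle genes showed no shift as a list: 6 of 35 rose and 5 fell (9 changed when adjusted over the list alone), with a mean of 0.01 (camera adjusted p = 0.936), a sign opposite to that of the camera test.

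Markers of other liver cells moved with these groups. Hepatocyte markers rose at 11 of 12 genes in Ets1/2 (11 when adjusted over the list alone), with a mean of 2.62 (camera adjusted p = 1.66e-09) and 0.85 against SHC202x2, and Ahsg, a protein hepatocytes secrete, rose 27.1-fold to 396 ± 32.1 from 14.6 ± 6.10. Endothelial markers rose at 9 of 13 with 2 falls (11 changed when adjusted over the list alone), with a mean of 1.06 (camera adjusted p = 0.00548, adjusted p = 0.065 with an estimated correlation), or 0.26 against SHC202x2. Macrophage markers split, with 9 of 17 up and 7 down (16 changed when adjusted over the list alone) and a mean of 0.90 (camera adjusted p = 0.0362, adjusted p = 0.292 with an estimated correlation), or 0.46 against SHC202x2. The complement gene C1qc rose 5.70-fold to 14800 ± 771, and the scavenger receptor Cd163 rose 10.1-fold. Against SHC202x2, 3298 of the 6637 genes (49.7%) changed again in the same direction and 79 in the opposite one. Cell cycle genes were lower against that control (mean log2 −0.82, camera adjusted p = 1.03e-23), and Ets1 was higher (log2 0.21, limma adjusted p = 0.00431).

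The Ets1 knockdown asked what this factor does alone. Inflammatory genes led the response: chemokines rose and targets of TGF-beta rose against both controls. Interferon-stimulated genes and collagens rose against SHC002. Of 3843 genes past limma adjusted p 0.05, 2018 rose and 1825 fell, and 593 changed by at least 2-fold.

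Chemokines and inflammatory mediators rose at 17 of 24 with no falls (20 changed when adjusted over the list alone), with a mean of 1.29 (camera adjusted p = 7.57e-15) and 1.61 against SHC202. Cxcl2, which attracts neutrophils, rose 10.7-fold, and Irg1, the itaconate-making enzyme of inflamed myeloid cells, rose 29.7-fold to 632 ± 21.2 (n = 2) from 21.3 (n = 1). TGF-beta targets rose at 9 of 20 with 2 falls (13 changed when adjusted over the list alone), with a mean of 0.52 (camera adjusted p = 4.81e-05) and 0.55 against SHC202. Tgfbi, a matrix protein TGF-beta induces, rose 20.4-fold, from 124. Of 25 activation markers, 15 rose and 2 fell (19 changed when adjusted over the list alone), with a mean of 0.43 (camera adjusted p = 2.96e-07). Timp1 rose 2.19-fold to 11348 ± 457 from 5173, while Acta2 fell. Interferon-stimulated genes rose at 30 of 32 (31 when adjusted over the list alone), with a mean of 1.22 (camera adjusted p = 5.73e-22, adjusted p = 0.0556 with an estimated correlation) and 0.28 against SHC202, and Ifi44 rose 5.16-fold. Collagens rose at 14 of 17 (14 when adjusted over the list alone, camera adjusted p = 4.34e-09, adjusted p = 0.0658 with an estimated correlation), with a mean of 0.60.

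Macrophage markers changed at 14 of 17 genes in the Ets1 knockdown, 10 up and 4 down (14 when adjusted over the list alone), and as a list did not pass the test (camera adjusted p = 0.0599). Aif1 rose (log2 3.47), while Marco fell 7.98-fold, Vsig4 fell 7.03-fold and Cd5l fell 5.71-fold. Against SHC202 the change of Aif1 was 1.07, that of Marco −0.795 and that of the list −0.555. Hepatocyte markers rose at 6 of 12 (6 when adjusted over the list alone), with a mean of 0.36 (camera adjusted p = 0.00846, adjusted p = 0.216 with an estimated correlation), or −0.29 against SHC202. Pparg fell 2.62-fold and Dio2 16.2-fold. Against SHC202, activation markers no longer passed (mean log2 0.10, camera adjusted p = 0.54). Quiescent HSC markers turned from 0.19 to −0.69 and collagens to −0.33. Col1a2 turned from log2 1.01 to −0.77 and Acta2 from −0.42 to 0.67. Of the 3843 genes, 2017 (52.5%) changed in the same direction against SHC202 and 344 in the opposite one.

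The Ets2 knockdown asked the same of Ets2. Collagens, contractile genes, activation markers and interferon-stimulated genes all rose, as in Ets1/2, and no tested collagen gene was left out. Of 4265 genes past limma adjusted p 0.05, 2163 rose and 2102 fell, and 874 changed by at least 2-fold. Collagens rose at 17 of 17 (17 when adjusted over the list alone), with a mean of 1.15 (camera adjusted p = 1.58e-17) and 0.23 against SHC202. Activation markers rose at 19 of 25 with 2 falls (21 changed when adjusted over the list alone), with a mean of 0.68 (camera adjusted p = 5.49e-13) and 0.35 against SHC202. Contractile genes rose at 11 of 17 with 1 fall (13 changed when adjusted over the list alone), with a mean of 0.52 (camera adjusted p = 1.10e-06, adjusted p = 0.135 with an estimated correlation), and 1.09 against SHC202. Cnn1 rose 3.35-fold to 1428 ± 50.3 (n = 2) from 426 (n = 1), and Acta2 rose 1.32-fold to 39193 ± 542 from 29642.

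Interferon-stimulated genes rose at 30 of 32 in the Ets2 knockdown (30 when adjusted over the list alone), with a mean of 1.40 (camera adjusted p = 5.50e-22, adjusted p = 0.0556 with an estimated correlation) and 0.45 against SHC202. Ifit1 rose 6.61-fold to 1307 ± 26.8 from 198, a log2 change of 2.72 that was 0.812 against SHC202. Chemokines rose at 11 of 24 with 3 falls (16 changed when adjusted over the list alone), with a mean of 0.61 (camera adjusted p = 8.54e-04, adjusted p = 0.259 with an estimated correlation) and 0.92 against SHC202. The acute-phase gene Saa3 rose 4.01-fold, and Il6 rose 2.96-fold to 263 ± 20.9 from 89.1. Hepatocyte markers rose at 9 of 12 (10 when adjusted over the list alone), with a mean of 1.51 (camera adjusted p = 3.79e-09) and 0.85 against SHC202. Endothelial markers rose at 9 of 13 with 2 falls (11 changed when adjusted over the list alone), with a mean of 1.10 (camera adjusted p = 0.00108) and 0.29 against SHC202. Macrophage markers rose at 8 of 17 with 5 falls (13 changed when adjusted over the list alone), with a mean of 0.61 (camera adjusted p = 0.00548, adjusted p = 0.178 with an estimated correlation) and −0.04 against SHC202. Bex1 fell 8.26-fold. Against SHC202, 1911 genes (44.8%) changed in the same direction and 300 in the opposite one, and the 4.65-fold rise of Col3a1 was gone (log2 −0.02, limma adjusted p = 0.967).

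The Gata4/6 comparison asked, by its label, what the Gata pair does in HSCs, though neither target was lower than in SHC002x2. Contractile genes, chemokines and genes of retinoid metabolism rose against both controls. Cd36 and Lpl, which take up fat, fell. The granule proteases Mcpt8 and Gzme were among the largest rises. Of 7033 genes past limma adjusted p 0.05, the most of any knockdown, 3804 rose and 3229 fell, and 1407 changed by at least 2-fold.

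Contractile genes rose at 16 of 17 in Gata4/6 with 1 fall (17 changed when adjusted over the list alone), with a mean of 0.73 (camera adjusted p = 8.97e-09, adjusted p = 0.0872 with an estimated correlation) and 0.42 against SHC202x2. Cnn1 rose 3.51-fold, Myh11, the smooth muscle myosin, rose 2.29-fold to 1526 ± 89.3 from 667 ± 55.8 (n = 2 each), and Acta2 rose 1.86-fold to 32957 ± 3520 from 17684 ± 832. Activation markers rose at 21 of 25 with 1 fall (22 changed when adjusted over the list alone), with a mean of 0.84 (camera adjusted p = 4.06e-12) and 0.18 against SHC202x2. Timp1 rose 2.21-fold to 6917 ± 699 from 3127 ± 277. Collagens rose at 17 of 17 (17 when adjusted over the list alone), with a mean of 1.21 (camera adjusted p = 1.32e-12). Col8a1 rose 4.62-fold to 1498 ± 33.1 from 324 ± 50.2, and Col1a2 rose 2.98-fold to 12928 ± 1060. TGF-beta targets rose at 13 of 20 with 2 falls (17 changed when adjusted over the list alone), with a mean of 0.48 (camera adjusted p = 7.01e-05) and 0.21 against SHC202x2. Ctgf, a growth factor of fibrosis, rose 2.02-fold to 37100 ± 606. Matrix genes rose at 25 of 30 with 2 falls (27 changed when adjusted over the list alone), with a mean of 0.77 (camera adjusted p = 5.76e-12) that was gone against SHC202x2 (−0.01). Thbs2 rose 4.35-fold, and Mmp13 fell 3.07-fold to 10446 ± 317.

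Retinoid genes rose at 12 of 18 in Gata4/6 with 2 falls (14 changed when adjusted over the list alone), with a mean of 0.69 (camera adjusted p = 0.00136) and 0.46 against SHC202x2. Rbp4, the retinol carrier of blood that hepatocytes secrete as well, rose 5.50-fold, and Aldh1a1, which makes retinoic acid, rose 3.79-fold to 596 ± 41.8 from 157 ± 11.8. Lrat, which makes the stored retinyl esters, did not pass (log2 0.23, limma adjusted p = 0.263) and was lower against SHC202x2 (log2 −0.94, limma adjusted p = 6.96e-05). Chemokines and inflammatory mediators rose at 22 of 24 with no falls (23 when adjusted over the list alone), with a mean of 1.38 (camera adjusted p = 1.10e-10, adjusted p = 0.058 with an estimated correlation) and 0.94 against SHC202x2. The neutrophil attractant Cxcl5 rose 8.35-fold to 406 ± 83.4 from 48.7 ± 13.7, and Lcn2, an iron-trapping defence protein, rose 6.25-fold, from 405 ± 12. Genes of the unfolded protein and integrated stress responses rose at 16 of 23 with 4 falls (20 changed when adjusted over the list alone), with a mean of 0.20 (camera adjusted p = 0.0162, adjusted p = 0.175 with an estimated correlation), or 0.26 against SHC202x2. Ddit4 rose 3.15-fold, whereas Atf3 fell 4.02-fold.

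Cd36 fell 4.36-fold in Gata4/6, to 12123 ± 1090 from 52819 ± 3240, and the lipase Lpl fell 4.12-fold to 5150 ± 665 from 21198 ± 169. Lipid droplet genes did not pass as a list, with 8 of 17 down and 6 up (14 changed when adjusted over the list alone) and a mean of −0.27 (camera adjusted p = 0.0817), or −0.26 against SHC202x2. Mamdc2 fell 13.8-fold to 143 ± 24.2 from 1968 ± 15.3, Dio2 fell 12.5-fold, and Cd207, a lectin of Langerhans cells, fell 12.9-fold. The granule protease Mcpt8 of basophils rose 14.0-fold to 603 ± 125 from 43 ± 7.25, and the cytotoxic granule protease Gzme rose 28.7-fold to 230 ± 90.4 from 8.03 ± 6.50 (log2 4.03 to 5.65 with a library left out). Their families hold close paralogs between which reads could be split. Hepatocyte markers rose at 10 of 12 in Gata4/6 (11 when adjusted over the list alone), with a mean of 1.49 (camera adjusted p = 4.74e-06, adjusted p = 0.058 with an estimated correlation), and turned to −0.28 against SHC202x2. Endothelial markers rose at 10 of 13 with 2 falls (12 changed when adjusted over the list alone), with a mean of 1.29 (camera adjusted p = 0.00173) and 0.49 against SHC202x2. Macrophage markers rose at 8 of 17 and fell at 8 (17 changed when adjusted over the list alone), with a mean of 0.27, a median of −0.12 and no call as a list (camera adjusted p = 0.911). Against SHC202x2 their mean was −0.17.

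Interferon-stimulated genes rose at 23 of 32 in Gata4/6 with 1 fall (24 changed when adjusted over the list alone, camera adjusted p = 6.40e-07, adjusted p = 0.251 with an estimated correlation), with a mean of 0.86. Against SHC202x2 this mean was −0.09, and the mean of the collagens was 0.07 (camera adjusted p = 0.253). Col1a2 turned to a log2 change of −0.28 (limma adjusted p = 0.0382). Of the 7033 genes, 4484 (63.8%) changed in the same direction against SHC202x2 and 246 in the opposite one.

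The Gata4 knockdown asked what Gata4 does alone. Chemokines and activation markers rose against both controls, and proliferation genes rose against SHC002 alone. Of 4714 genes past limma adjusted p 0.05, 2468 rose and 2246 fell, and 874 changed by at least 2-fold. Activation markers rose at 22 of 25 with 1 fall (23 changed when adjusted over the list alone), with a mean of 0.73 (camera adjusted p = 1.78e-13) and 0.40 against SHC202. Timp1 rose 2.23-fold to 11520 ± 339 (n = 2) from 5173 (n = 1), and Postn rose 2.96-fold. Contractile genes rose at 10 of 17 with 1 fall (11 changed when adjusted over the list alone), with a mean of 0.25 (camera adjusted p = 0.00906, adjusted p = 0.389 with an estimated correlation) and 0.82 against SHC202. Chemokines rose at 13 of 24 with 1 fall (15 changed when adjusted over the list alone), with a mean of 0.72 (camera adjusted p = 7.26e-07, adjusted p = 0.118 with an estimated correlation) and 1.04 against SHC202. Ccl2, the main attractant of monocytes, rose 4.41-fold to 9570 ± 305 from 2171, Ccl7 rose 5.18-fold to 4710 ± 462 from 910, and Ccl12 rose 11.9-fold.

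Portal fibroblast and smooth muscle markers rose at 8 of 9 in the Gata4 knockdown (8 when adjusted over the list alone, camera adjusted p = 1.64e-05), with a mean of 1.07, or 0.67 against SHC202. Mgl2, a lectin of alternatively activated macrophages, rose 107-fold to 624 ± 68.6 from 5.81, and the resident macrophage receptor Marco fell 8.35-fold. Lipid droplet genes fell at 6 of 17 and rose at 4 (10 changed when adjusted over the list alone), with a mean of −0.28 (camera adjusted p = 0.0415, adjusted p = 0.0872 with an estimated correlation), or −0.42 against SHC202. Plin2, which coats lipid droplets, fell 2.92-fold to 12076 ± 761 from 35273. Kcna2, a potassium channel, fell 40.2-fold, and Ets2 rose 1.85-fold. Hepatocyte markers rose at 7 of 12 (7 when adjusted over the list alone), with a mean of 0.69 (camera adjusted p = 3.65e-04, adjusted p = 0.114 with an estimated correlation), or 0.03 against SHC202. Cell cycle genes rose at 33 of 35 (35 changed when adjusted over the list alone), with a mean of 0.89 (camera adjusted p = 3.78e-18), but turned to −0.17 against SHC202. Macrophage markers turned as well, from 0.25 to −0.40, and 2284 genes (48.5%) changed in the same direction against SHC202 with 343 in the opposite one.

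The Gata6 label asked what Gata6 does alone, though only the SHC002 control held more Gata6. Proliferation genes fell against either control, the reverse of what Gata4 knockdown gave against SHC002, while collagens and interferon-stimulated genes rose. Of 4069 genes past limma adjusted p 0.05, 1859 rose and 2210 fell, and 585 changed by at least 2-fold. Cell cycle genes fell at 31 of 35 (32 when adjusted over the list alone), with a mean of −0.69 (camera adjusted p = 4.52e-16) and −1.75 against SHC202. Plk1, a kinase of mitosis, fell 2.64-fold to 77 ± 8.5 (n = 2) from 203 (n = 1), and Ccna2, the cyclin of S phase, fell 2.34-fold. Cd36 fell 3.82-fold to 10055 ± 1120 from 38420 and Lpl fell 3.60-fold. Lipid droplet genes as a list did not pass, with 5 of 17 down and 3 up (8 changed when adjusted over the list alone) and a mean of −0.26 (camera adjusted p = 0.138), or −0.39 against SHC202. The matrix protease Mmp9 fell 8.74-fold to 33.2 ± 6.63 from 290, and Cd207 fell 12.3-fold. Kdr, a receptor for vascular endothelial growth factor, rose 5.32-fold to 2205 ± 29.8 from 415, among endothelial markers that rose at 6 of 13 with 2 falls (10 changed when adjusted over the list alone, camera adjusted p = 0.00897, adjusted p = 0.0767 with an estimated correlation), with a mean of 0.93.

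Interferon-stimulated genes rose at 30 of 32 in the Gata6 knockdown (31 when adjusted over the list alone), with a mean of 1.36 (camera adjusted p = 1.03e-24) and 0.42 against SHC202. Contractile genes rose at 11 of 17 with 1 fall (12 changed when adjusted over the list alone), with a mean of 0.24 (camera adjusted p = 7.63e-04, adjusted p = 0.269 with an estimated correlation) and 0.81 against SHC202. Collagens rose at 16 of 17 (16 when adjusted over the list alone), with a mean of 0.85 (camera adjusted p = 8.32e-14). Among activation markers 16 of 25 rose and 2 fell (18 changed when adjusted over the list alone), with a mean of 0.40 (camera adjusted p = 2.71e-07). Hepatocyte markers fell at 5 of 12 and rose at 1 (8 changed when adjusted over the list alone), with a mean of −0.67 (camera adjusted p = 0.00964, adjusted p = 0.22 with an estimated correlation), or −1.32 against SHC202. Vsig4 fell 3.97-fold. Against SHC202, the mean of the collagens was −0.08 (camera adjusted p = 0.892), that of the activation markers 0.07 (camera adjusted p = 0.766) and that of the endothelial markers 0.12. In the same direction, 2584 genes (63.5%) changed against SHC202, and 280 changed in the opposite one.

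The Irf1/2 comparison asked what the interferon regulatory factors do in HSCs. Antigen presentation by MHC class I fell against both controls, together with proliferation genes, while chemokines rose. Interferon-stimulated genes fell, but only against SHC202x2. Activation markers did not shift as a list against SHC202x2 and rose against SHC002x2. Of 4451 genes past limma adjusted p 0.05, 2001 rose and 2450 fell, and 658 changed by at least 2-fold.

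MHC class I antigen presentation genes fell at 13 of 15 in Irf1/2 (13 when adjusted over the list alone), with a mean of −0.42 (camera adjusted p = 1.04e-06, adjusted p = 0.084 with an estimated correlation) and −0.32 against SHC002x2. Psmb9, a subunit of the immunoproteasome, fell 1.85-fold to 111 ± 0.78 from 206 ± 35.7 (n = 2 each), and its partner Psmb8 fell 1.55-fold to 591 ± 7.62 from 916 ± 44.6. Erap1, which trims peptides for class I loading, fell 1.84-fold to 971 ± 53.2 from 1789 ± 39.9. Cell cycle genes fell at 34 of 35 (34 when adjusted over the list alone), with a mean of −1.01 (camera adjusted p = 7.23e-27) and −0.18 against SHC002x2. Ccna2 fell 2.95-fold against SHC202x2 and did not pass against SHC002x2 (limma adjusted p = 0.25). Cholesterol synthesis genes fell at 13 of 20 and rose at 1 (15 changed when adjusted over the list alone), with a mean of −0.22 (camera adjusted p = 4.93e-04, adjusted p = 0.0749 with an estimated correlation), or −0.16 against SHC002x2. Hmgcs1, an early enzyme of that pathway, fell 1.73-fold.

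Chemokines rose at 13 of 24 in Irf1/2 with 3 falls (16 changed when adjusted over the list alone), with a mean of 0.54 (camera adjusted p = 2.93e-05, adjusted p = 0.173 with an estimated correlation) and 0.97 against SHC002x2. The neutrophil attractants Cxcl5 and Cxcl1 rose 9.48-fold and 4.79-fold, Cxcl5 to 361 ± 40.1 from 38.1 ± 24.7 (log2 2.67 to 4.06 with a library left out). Ptgs2, the inducible enzyme of prostaglandin synthesis, rose 4.48-fold to 9473 ± 319 from 2116 ± 491. Contractile genes rose at 11 of 17 with 2 falls (14 changed when adjusted over the list alone), with a mean of 0.22 (camera adjusted p = 7.52e-04, adjusted p = 0.269 with an estimated correlation) and 0.53 against SHC002x2. Acta2 rose 1.35-fold to 30287 ± 1600 from 22369 ± 292. Spp1, the matricellular protein osteopontin, fell 2.35-fold to 67210 ± 3840 from 158180 ± 8880. Lpl fell 2.99-fold, Arg2 rose 7.12-fold and Marco rose 6.07-fold to 3207 ± 53.3 from 528 ± 41.4.

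Interferon-stimulated genes fell at 28 of 32 in Irf1/2 (30 when adjusted over the list alone), with a mean of −0.998 (camera adjusted p = 2.21e-17, adjusted p = 0.0776 with an estimated correlation). Mx1 fell 6.26-fold to 6.49 ± 2.32 from 40.6 ± 21.1, and Ifit3 fell 4.46-fold to 80.8 ± 4.08 from 360 ± 51.5. Interferon-gamma-induced genes fell at 9 of 12 (10 changed when adjusted over the list alone), with a mean of −0.70 (camera adjusted p = 4.28e-05, adjusted p = 0.0872 with an estimated correlation). Collagens fell at 9 of 17 and rose at 2 (13 changed when adjusted over the list alone), with a mean of −0.37 (camera adjusted p = 0.00456, adjusted p = 0.304 with an estimated correlation), and Col1a2 fell 1.95-fold to 8073 ± 852 from 15699 ± 1010. Macrophage markers fell at 11 of 17 and rose at 2 (14 changed when adjusted over the list alone), with a mean of −0.33 (camera adjusted p = 4.54e-05, adjusted p = 0.0724 with an estimated correlation). Activation markers fell at 12 of 25 and rose at 7 (20 changed when adjusted over the list alone), with a mean of −0.16 (camera adjusted p = 0.153). Against SHC002x2, interferon-stimulated genes had a mean of −0.05 (camera adjusted p = 0.367) and Mx1 did not pass (limma adjusted p = 0.433). Against that control collagens were at 0.76, Col1a2 at 0.89, Col1a1 at 0.64 in place of −0.57, activation markers at 0.50 (camera adjusted p = 4.09e-10), interferon-gamma-induced genes at 0.21 and macrophage markers at 0.11. Of the 4451 genes, 2421 (54.4%) changed in the same direction against SHC002x2 and 252 in the opposite one.

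**Figure D3:**
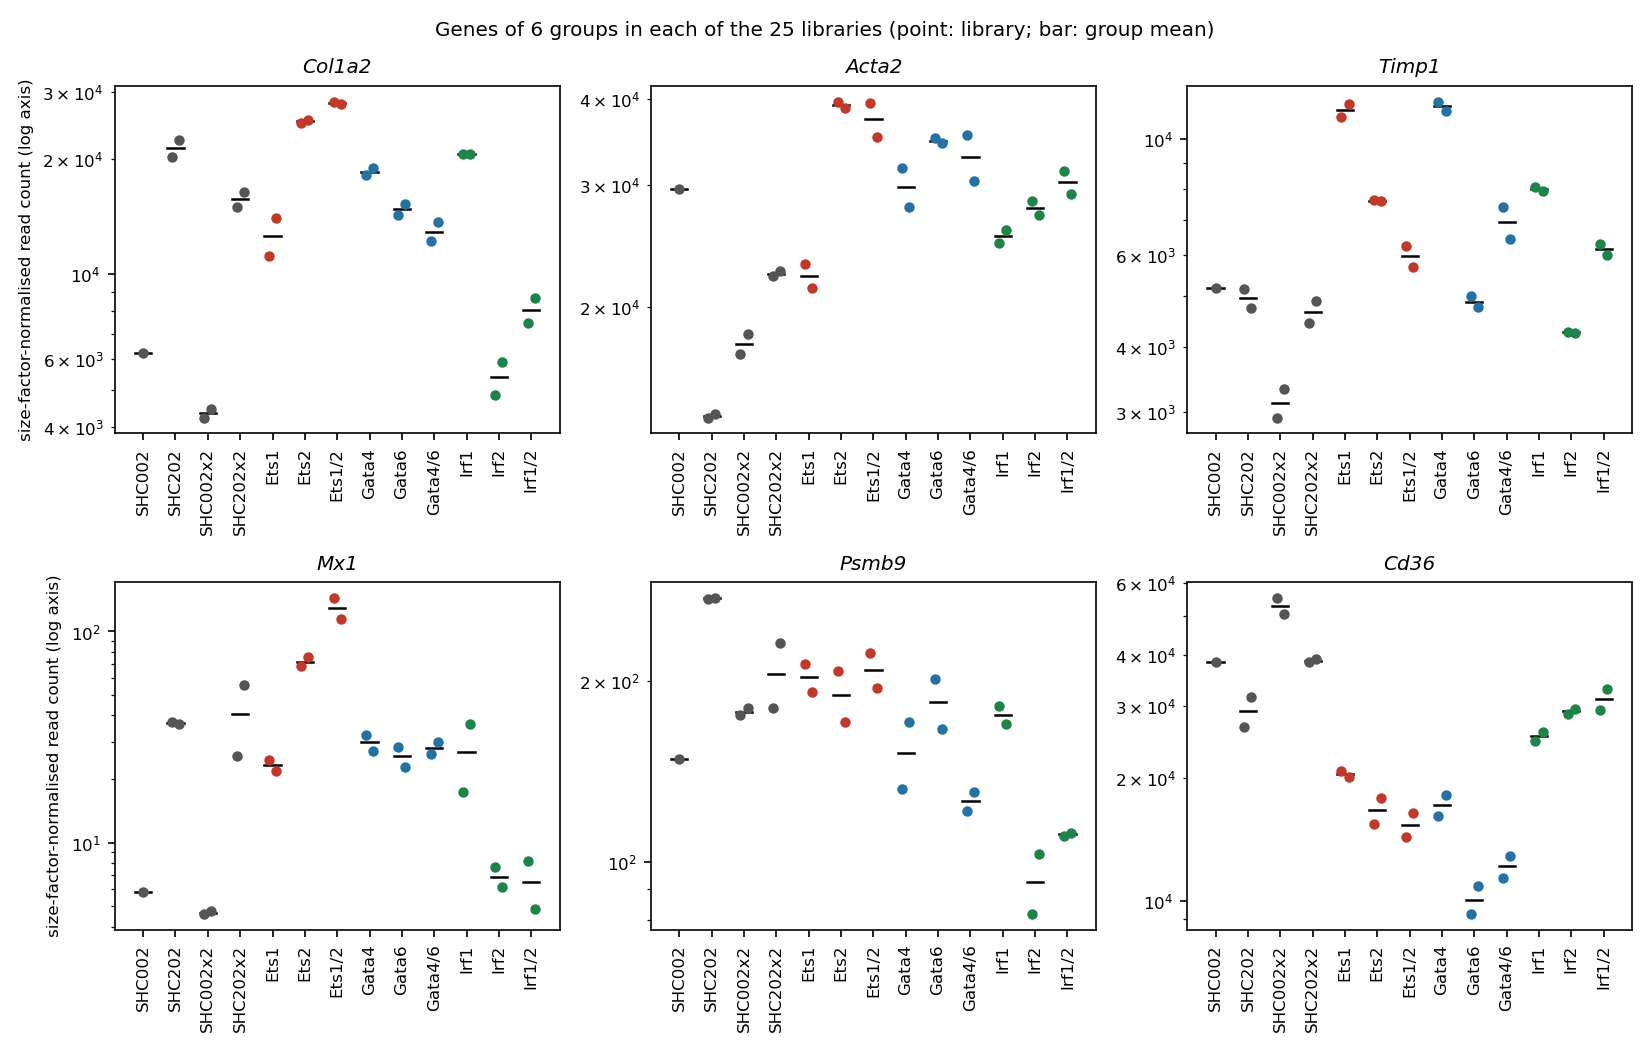
Size-factor-normalised read counts (vertical axes, log scale) of Col1a2, Acta2, Timp1, Mx1, Psmb9 and Cd36 in the 13 groups of RNA libraries. Each point is a library and each bar a group mean, and Col1a2 spans 4333 in SHC002x2 to 27988 in Ets1/2.

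The Irf1 knockdown asked what Irf1 does alone. Chemokines and activation markers rose, with fewer changes of 2-fold or more than in any other knockdown, and proliferation genes fell against SHC202 alone. Of 3957 genes past limma adjusted p 0.05, 1941 rose and 2016 fell, and 364 changed by at least 2-fold. Without shIrf1 replicate 2 the count was 2573. Egr1, an immediate-early transcription factor, rose 5.68-fold to 1887 ± 62.8 from 333 ± 2.79 (n = 2 each), and log2 2.15 of this held against SHC002. Timp1 rose 1.62-fold to 8014 ± 105 from 4957 ± 284. Among activation markers 10 of 25 rose and 3 fell (13 changed when adjusted over the list alone), with a mean of 0.22 (camera adjusted p = 8.54e-04, adjusted p = 0.142 with an estimated correlation) and 0.55 against SHC002. Chemokines rose at 14 of 24 with 2 falls (18 changed when adjusted over the list alone), with a mean of 0.58 (camera adjusted p = 1.22e-07, adjusted p = 0.0967 with an estimated correlation) and 0.27 against SHC002. Matrix genes rose at 10 of 30 with 4 falls (15 changed when adjusted over the list alone, camera adjusted p = 0.0334, adjusted p = 0.445 with an estimated correlation), with a mean of 0.10, or 0.60 against SHC002.

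Cell cycle genes fell at 31 of 35 in the Irf1 knockdown (32 when adjusted over the list alone), with a mean of −0.72 (camera adjusted p = 2.79e-23), but were higher against SHC002 (mean log2 0.34, camera adjusted p = 2.72e-05). Mki67, a marker of dividing cells, fell 2.20-fold to 2387 ± 10.1 from 5251 ± 129 and turned to a log2 change of 0.55 against SHC002. Ptgs2 rose 4.76-fold to 2279 ± 90.9 from 479 ± 89.7 and turned to −0.79. Siglec5 fell 3.77-fold, and Marco rose 5.83-fold against SHC202 alone (limma adjusted p = 0.317 against SHC002). Of the 3957 genes, 1383 (35.0%) changed in the same direction against SHC002 and 503 in the opposite one.

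The Irf2 knockdown asked what Irf2 does alone. Antigen presentation genes fell against both controls, as in Irf1/2. Macrophage markers fell, and against SHC202 collagens, activation markers and proliferation genes fell with them. Of 6081 genes past limma adjusted p 0.05, 2851 rose and 3230 fell, and 1190 changed by at least 2-fold. MHC class I antigen presentation genes fell at 12 of 15 and rose at 1 (13 changed when adjusted over the list alone), with a mean of −0.59 (camera adjusted p = 6.86e-07, adjusted p = 0.0794 with an estimated correlation) and −0.24 against SHC002. Psmb9 fell 2.97-fold to 92.4 ± 15.1 from 274 ± 0.31 (n = 2 each). Macrophage markers fell at 15 of 17 and rose at 1 (16 changed when adjusted over the list alone), with a mean of −1.14 (camera adjusted p = 3.57e-12) and −0.50 against SHC002. Cd163 fell 18.7-fold to 5.62 ± 0.73 from 105 ± 3.76. Hepatocyte markers fell at 10 of 12 (10 when adjusted over the list alone), with a mean of −1.35 (camera adjusted p = 6.79e-06, adjusted p = 0.0607 with an estimated correlation) and −0.69 against SHC002. Targets of p53 rose at 12 of 16 with no falls (12 when adjusted over the list alone), with a mean of 0.47 (camera adjusted p = 2.03e-07) and 0.10 against SHC002. Mdm2, the ubiquitin ligase of p53, rose 2.02-fold, from 5258 ± 331.

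Collagens fell at 14 of 17 in the Irf2 knockdown and rose at 1 (17 changed when adjusted over the list alone), with a mean of −1.12 (camera adjusted p = 2.58e-10, adjusted p = 0.0556 with an estimated correlation) and −0.19 against SHC002. Col3a1 fell 6.89-fold to 3596 ± 1140 from 24758 ± 1720, and Col1a2 fell 3.96-fold to 5379 ± 761 from 21306 ± 1570. Neither passed against SHC002 (limma adjusted p = 0.227 and 0.333). Activation markers fell at 16 of 25 and rose at 5 (21 changed when adjusted over the list alone), with a mean of −0.45 (camera adjusted p = 3.65e-04, adjusted p = 0.122 with an estimated correlation), or −0.12 against SHC002. Acta2 went the other way, rising 2.00-fold to 27823 ± 945 from 13938 ± 116, and did not pass against SHC002 (limma adjusted p = 0.556). Cell cycle genes fell at 34 of 35 (34 when adjusted over the list alone), with a mean of −1.02 (camera adjusted p = 2.27e-20) that turned to 0.04 against SHC002. Interferon-stimulated genes fell at 23 of 32 and rose at 2 (26 changed when adjusted over the list alone), with a mean of −0.70 (camera adjusted p = 9.44e-08, adjusted p = 0.22 with an estimated correlation), and turned to 0.24 against SHC002. Chemokines rose at 11 of 24 with 5 falls (17 changed when adjusted over the list alone, camera adjusted p = 0.00455, adjusted p = 0.331 with an estimated correlation), with a mean of 0.47 that ran from 0.273 to 0.659 with a library left out, or 0.15 against SHC002. Ptgs2 rose 11.6-fold to 5570 ± 92.0 from 479 ± 89.7 and Serpina3n fell 61.2-fold to 15.0 ± 4.89 from 915 ± 45, and neither passed against SHC002 (limma adjusted p = 0.105 and 0.421). Of the 6081 genes, 812 (13.4%) changed in the same direction against SHC002, where only 1247 genes passed at all, and 87 changed in the opposite one.

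Comparing the 2 single knockdowns of a family asked what its members do differently, without any control in the contrast. Loss of Ets1 left contractile and collagen genes lower than loss of Ets2, and inflammatory and TGF-beta genes higher. Between them, 4970 genes differed, 2504 higher and 2466 lower with Ets1 knockdown. Contractile genes were lower at 13 of 17 and higher at 2 (mean log2 −0.52, camera adjusted p = 1.61e-07, adjusted p = 0.174 with an estimated correlation), and Acta2 was 1.77-fold lower. Collagens were lower at 14 of 17 (mean log2 −0.55, camera adjusted p = 4.19e-08, adjusted p = 0.129 with an estimated correlation), and Col1a2 was 1.99-fold lower. TGF-beta targets were higher at 13 of 20 (mean log2 0.46, camera adjusted p = 6.06e-06), and chemokines at 13 of 24, or 14 when adjusted over the list alone (mean log2 0.69, camera adjusted p = 5.72e-06, adjusted p = 0.177 with an estimated correlation). Among the largest differences, Treml4 was 24.2-fold higher (1274 ± 39.6 against 52.7 ± 3.72, n = 2 each), the cystine transporter Slc7a11 was 17.2-fold higher and Cd163 was 7.30-fold lower.

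Gata4 and Gata6 knockdowns, the latter with no clear fall of Gata6, differed most in proliferation. All 35 cell cycle genes were higher with Gata4 knockdown (mean log2 1.58, camera adjusted p = 1.43e-31). Interferon-stimulated genes were lower at 30 of 32 (mean log2 −0.98, camera adjusted p = 5.93e-15, adjusted p = 0.155 with an estimated correlation), and matrix genes were higher at 17 of 30 and lower at 5 (mean log2 0.52, camera adjusted p = 5.93e-05, adjusted p = 0.206 with an estimated correlation). Activation markers were higher at 14 of 25, or 15 when adjusted over the list alone (mean log2 0.33, camera adjusted p = 4.02e-04, adjusted p = 0.177 with an estimated correlation), and Timp1 was 2.36-fold higher. Pparg was 2.89-fold lower. Among 5832 genes that differed, 3164 higher and 2668 lower, Mgl2 stood at 624 ± 68.6 against 4.01 ± 0.09, Mmp9 was 23.7-fold higher, and Card14 was 45.3-fold lower.

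Irf1 knockdown left fibrogenic and macrophage genes higher than Irf2 knockdown did. Collagens were higher at 17 of 17 (mean log2 1.21, camera adjusted p = 1.77e-15), with Col1a2 3.84-fold higher (20664 ± 6.02 against 5379 ± 761, n = 2 each) and Col1a1 2.76-fold higher. Matrix genes were higher at 25 of 30, or 26 when adjusted over the list alone (mean log2 0.74, camera adjusted p = 3.50e-14), and activation markers at 19 of 25 (mean log2 0.67, camera adjusted p = 2.16e-09). Macrophage markers were higher at 13 of 17, or 14 when adjusted over the list alone (camera adjusted p = 6.48e-12), and Cd163 was 27.4-fold higher. Targets of p53 were lower at 10 of 16 (mean log2 −0.24, camera adjusted p = 4.72e-04). In all, 5692 genes differed, 3062 higher and 2630 lower.

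The pair knockdowns were also set beside the singles and beside each other. Across genes, which are not independent replicates, the changes in Ets1/2 followed those in the Ets2 knockdown (Pearson r = 0.798) more than those in the Ets1 knockdown (r = 0.511). Changes in the Gata4 knockdown, which targets no Ets gene, reached r = 0.563 with Ets1/2, above Ets1. All of these changes were taken against the SHC002 hairpin, whose own effect they share. Gata4/6 resembled its singles about equally (r = 0.566 for Gata4 and 0.558 for Gata6), and Irf1/2 was closer to Irf1 (r = 0.676) than to Irf2 (r = 0.555). With SHC202x2 as the control of all 3 pairs, the mean change of the activation markers was 0.40 in Ets1/2, 0.18 in Gata4/6 and −0.16 in Irf1/2. Ets1/2 exceeded Gata4/6 at 15 of 25 of these genes (difference 0.219, camera adjusted p = 0.00648, adjusted p = 0.209 with an estimated correlation). Interferon-stimulated genes separated Ets1/2 from Gata4/6 more clearly, at 30 of 32 genes (difference 1.15, camera adjusted p = 8.78e-15, adjusted p = 0.108 with an estimated correlation).

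Macrophage transcripts were abundant in every library. The lysosomal and macrophage genes Ctsd, Gpnmb, Ftl1, Ctsb, Psap, Mmp12 and Lyz2 were the 7 genes with the highest mean value, and Lyz2 averaged 127840 (94065 to 177250 over the means of the 13 groups). Gpnmb ran from 142660 in Ets1/2 to 365960 in SHC002x2 and Mmp12 from 50246 to 234320 in the same groups, so these genes were highest in the control against which collagens rose. Ctsd and Ptprc were highest in SHC002x2 as well, whereas Csf1r and Cd68 were highest in SHC202. Acta2 ranked 45 with a mean of 27879 and Col1a1 ranked 56 with a mean of 24526. Csf1r, the receptor that macrophages need to survive, ranked 112 with a mean of 15558. The hepatocyte gene Alb averaged 771, the endothelial gene Stab2 averaged 114 and Pecam1 averaged 13.7. The values do not say which cells made a transcript, so a change in a macrophage, hepatocyte or endothelial gene is a change in the library as a whole.

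Mouse HSC chromatin was compared between stages to ask which sites appear with activation and which persist after recovery. More H3K27ac peaks were called in activated than in quiescent HSCs, though the quiescent library also had the fewest tags in peaks. H3K27ac peaks numbered 21188 in quiescent and 52173 in activated HSCs, 44038 after 1 week of recovery and 40103 after 1 month. H3K4me2 peaks went the other way, from 60844 in quiescent to 49115 in activated HSCs, with 48249 and 48722 in recovery. H3K4me2 peaks covered 100 Mb in quiescent and 77.3 Mb in activated HSCs, with 60.72% and 48.60% of tags in peaks. The share of tags in H3K27ac peaks was 4.90% in quiescent and 37.95% in activated HSCs, 24.76% at 1 week and 11.69% at 1 month. Of the quiescent H3K27ac peaks, 16146 (76.2%, 95% exact interval 75.6 to 76.8) overlapped an activated peak, against 6.75% when the list was moved by 1 Mb. Of the activated H3K27ac peaks, 27.2% overlapped a quiescent peak (2.61% when moved). For H3K4me2, 63.3% of quiescent peaks (63.0 to 63.7) overlapped an activated peak (8.14% when moved), and 81.4% of activated peaks overlapped a quiescent one.

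Peaks kept on activation were called in both lists and those gained in 1, which favours kept peaks in recovery. Of 37956 H3K27ac peaks found in activated but not quiescent HSCs, 45% overlapped a peak at 1 week and 34.0% at 1 month (4.31% when moved), whereas 92.2% and 83.7% of the 16146 kept peaks did. Of 9127 H3K4me2 peaks gained on activation, 18.8% were overlapped at 1 week and 19.2% (18.4 to 20.0) at 1 month (6.50% when moved). Hepatocyte genes gained H3K4me2 too (below), so the cells behind gained peaks are uncertain. Of 22300 H3K4me2 peaks lost on activation, 24.9% (24.4 to 25.5) were overlapped again at 1 week and 33.9% (33.2 to 34.5) at 1 month (5.90% when moved). For longer peaks alone the 1 month share was 63.8%, and 53.5% for gained H3K27ac peaks. Of 5042 lost H3K27ac peaks, 26.5% were overlapped at 1 week and 17.8% at 1 month (3.67% when moved). Tags in peaks also rose for H3K4me2 and fell for H3K27ac, which could shift these shares. Intervals cover counting error only, without replicates.

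**Figure D4:**
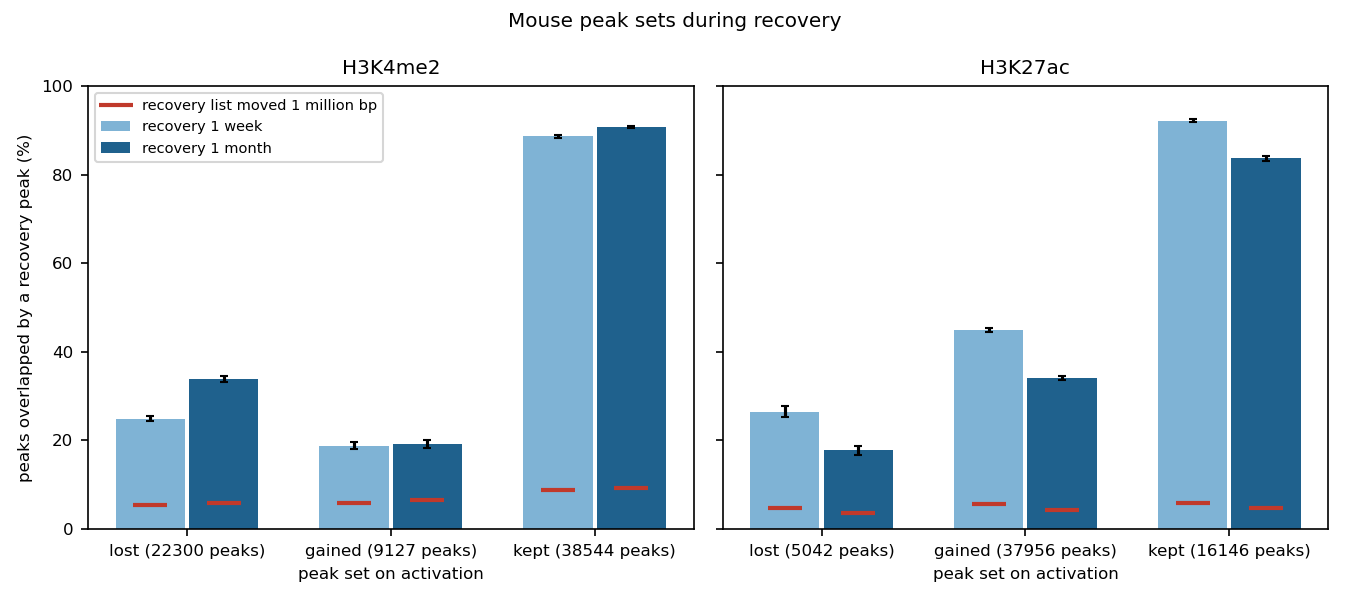
Percent (vertical axes) of the H3K4me2 and H3K27ac peaks lost, gained or kept on activation that overlapped a peak after 1 week or 1 month of recovery. Bars carry 95% exact binomial intervals, red lines give the value with the list moved 1 Mb, and 34.0% of gained H3K27ac peaks were overlapped at 1 month.

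Quiescent HSC markers had H3K27ac peaks at all stages, and activation markers gained them among many other genes. Of 18020 genes with a position, 51% had an H3K27ac peak within 2000 bp in quiescent HSCs, 70.9% in activated HSCs, 68.1% after 1 week and 64.2% after 1 month. Within 2000 bp of the gene, 12 of 25 activation markers had an H3K27ac peak in quiescent HSCs and 24 in activated HSCs, with 23 after 1 week and 24 after 1 month. Collagen genes went from 10 of 17 to 16, contractile genes from 9 of 17 to 15 and cell cycle genes from 13 of 35 to 31, and of these lists only cell cycle genes fell back, to 24 at 1 month. Of 28 quiescent HSC markers, 26 had a quiescent H3K27ac peak. All 15 MHC class I genes and 31 of 35 HSC transcription factors had one too. Of 18 hepatocyte marker genes, 7 had an H3K4me2 peak in quiescent HSCs, 18 in activated HSCs, 7 after 1 week and 15 after 1 month. With H3K4me2, 25 of 25 activation markers, 28 of 28 quiescent markers and 81.2% of all genes were marked in quiescent HSCs. Random genes of matched length gave a median of 15 (10 to 20 in the middle 95% of draws) in place of 26 quiescent markers. As many or more were reached in 0.01% of 10000 draws (permutation p = 0.0002). Of the activation markers 24 entered the draws, with a median of 13 in place of 12.

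At Col1a2 (GRCm38/mm10 chromosome 6, 4505618 to 4541543), H3K27ac covered 1.63% of the gene and its 2000 bp flanks in quiescent HSCs, 53.5% in activated HSCs, 12.3% after 1 week and 9.45% after 1 month. H3K4me2 covered 12.9%, 19.6%, 25.7% and 13.7%. At Acta2 (chromosome 19, 34240336 to 34255585) no H3K27ac peak was called in quiescent HSCs, while 32.6% was covered in activated HSCs and 12.8% at 1 month. Lrat (chromosome 3, 82892582 to 82903974) gained H3K27ac as well, from 5.18% to 53.9%, while its H3K4me2 cover stayed at 70.5% to 81.8% throughout. All 6 targeted genes had less H3K4me2 cover in activated than in quiescent HSCs, as the mark had over all peaks, and more H3K27ac cover. H3K4me2 cover went at Ets1 (chromosome 9, 32636241 to 32757820) from 61.0% to 40.3% and back to 57.0% at 1 month, and at Gata4 (chromosome 14, 63198914 to 63271712) from 71.0% to 51.2% and back to 65.0%. At Gata6 (chromosome 18, 11052510 to 11085636) it went from 58.6% to 42.5%, then to 61.9% at 1 week and 43.5% at 1 month.

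**Figure D5:**
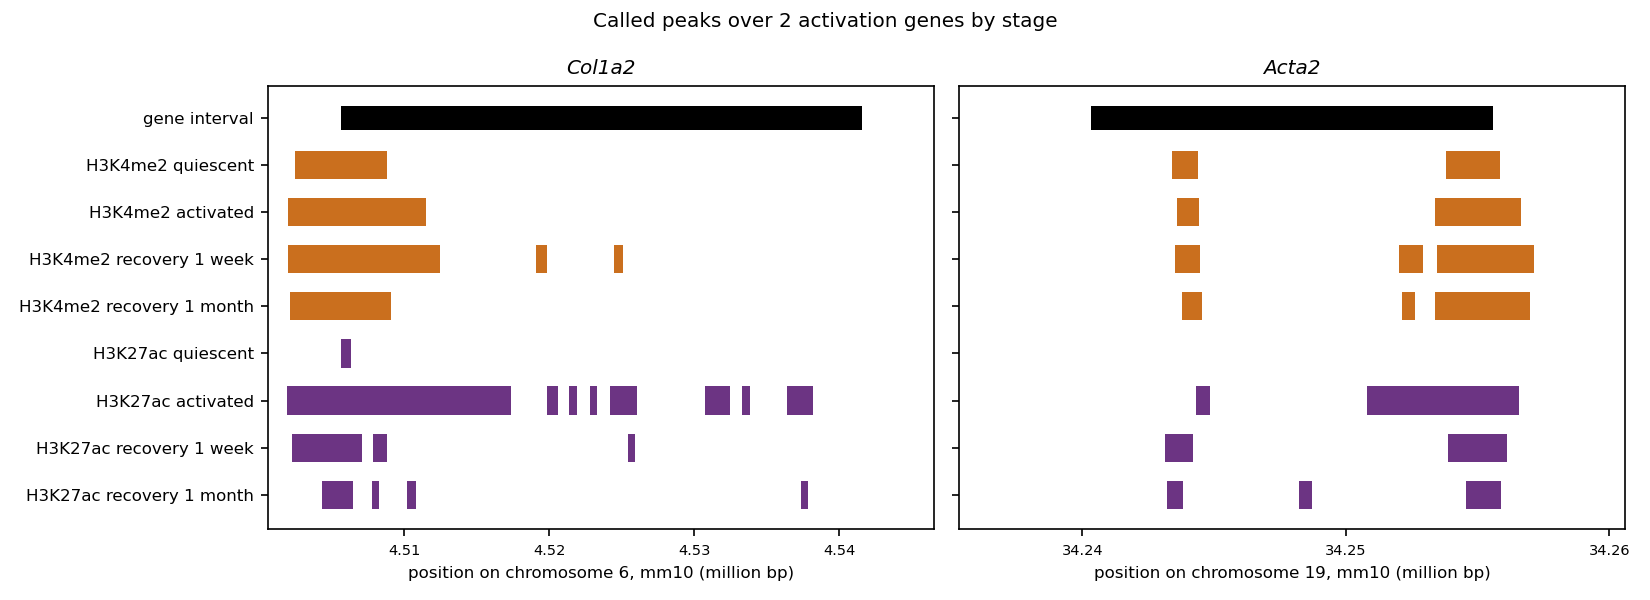
Called H3K4me2 and H3K27ac peaks (bars) by stage at Col1a2 on chromosome 6 and Acta2 on chromosome 19, with position in GRCm38/mm10 on the horizontal axes. Activated HSCs had 8 H3K27ac peaks at Col1a2, and quiescent HSCs had 1.

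Human HSCs were compared between sources and marks to ask how far their regulatory sites are shared. Only autosomal peaks were used. H3K4me2 peaks numbered 78075 in source 1 and 85603 in source 2. Of source 1 peaks, 82.6% (95% exact interval 82.3 to 82.9) overlapped a source 2 peak, against 10.5% when the list was moved by 1 Mb. In the other direction the share was 70.5%. H3K27ac peaks numbered 53909 and 57158, with 79.4% of source 1 peaks overlapped (8.53% when moved) and 75.7% in the other direction. H3K27ac overlapped 63.5% of H3K4me2 peaks in source 1 and 56.8% in source 2. In mouse HSCs this share was 24.6% in quiescence, 61.1% on activation, 58.7% after 1 week and 48.9% after 1 month.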

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

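Of the tests weighed in this part, those of macrophage content, of exchanged hairpins, of tags in peaks and of acetylation at quiescence genes were chosen only after the result was seen. All 10 results listed here were picked out because a difference between groups passed its test where the groups might have been alike. The change from 1 to 2 vectors differed between the control hairpins in 1421 genes. The changes in Ets1/2 and Gata4/6 differed in 6689 genes and by 0.219 in the mean of the activation markers, those in Ets1/2 and Irf1/2 in 6176 genes and by 1.22, and those in Gata4/6 and Irf1/2 in 5298 genes and by 0.997. Irf1/2 was taken against SHC202x2 and the other pairs against SHC002x2, so both differences from Irf1/2 include the difference between the control hairpins. With SHC202x2 as the control of all 3, the means of the activation markers were 0.40 in Ets1/2, 0.18 in Gata4/6 and −0.16 in Irf1/2. Within families, Ets1 and Ets2 knockdowns differed in 4970 genes, Gata4 and Gata6 knockdowns in 5832, and Irf1 and Irf2 knockdowns in 5692.

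The control hairpins SHC002 and SHC202 differed in 4292 genes as single vectors and 4098 as double vectors. An odd SHC002 library is argued against by the double vectors, whose differences had r = 0.605 with those of the single vectors across genes. Unequal depth is argued against by thinning, after which 82.3% of the calls between the double vectors were made again in the same direction. Fewer macrophages in SHC002 would leave HSC genes higher there, yet collagens were lower (mean log2 −1.13). A larger macrophage share in SHC002x2, where Gpnmb and Mmp12 were highest while the macrophage list was lower (mean log2 −0.44), stays open with effects of the hairpin sequences, the vector batch and the cell isolation, and no biological explanation was tested.

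Gata4 and Gata6 were not lower in Gata4/6 than in SHC002x2, and Ets1 was not lower in Ets1/2. A low SHC002x2 level could explain Gata4. Against the 9 groups with no Gata hairpin other than SHC002x2, it was at log2 −0.574 (limma adjusted p = 1.63e-10). Gata6 was at −0.198 (limma adjusted p = 0.00952) but no lower than in SHC202x2 (log2 0.013), so its case stays open. Exchanged hairpins are argued against, as 0 of the 4 other targeted genes were at or below their own knockdown level in Gata4/6. A low Ets1 in SHC002x2 is argued against for Ets1/2, where Ets1 stood at log2 0.0195 from the other groups (limma adjusted p = 0.729). Whether the Ets1 hairpin was absent or inactive in those libraries stays open, and protein was not measured.

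The activated H3K27ac list held 52173 peaks and the quiescent list 21188. Few tags in peaks in the quiescent library could produce this, since the share of tags in peaks and the number of peaks ranked the 4 lists alike (Spearman rho 1), but the share rises with the number of peaks by construction, so the tables cannot tell. Whether peaks were lost at all genes alike cannot be told from the quiescent list. It held a peak at 26 of 28 quiescence genes and at 12 of 25 activation genes (Fisher's exact p = 5.01e-04). Activation genes were near the median of 13 for random genes of matched length and quiescence genes above theirs. Expression was unmatched, so neither is placed among expressed genes. With 1 library per stage, a weak immunoprecipitation of the quiescent library stays open, and no biological explanation was tested.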

How the results depend on the processing

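The other control hairpin, the longer peaks, the equal number of peaks and the gene intervals were alternatives chosen after seeing the data, and all others were fixed before. Results held under changes of method and moved with the choice of control. The 12 gene counts stayed within 1.5 times under a pseudocount of 5, no filter, quantile normalisation, edgeR, DESeq2 and a fit of only the groups compared. Of 88 list means, 83 to 88 kept sign and side of the threshold under these 6, and of 169 named values 167 to 169 did. The exception among targeted genes was Gata6 in Gata4/6, whose small rise lost its call under quantile normalisation (0.166), edgeR (0.172), DESeq2 (0.198) and the fit of only the groups compared (0.205). Lipid droplet genes, not called in Gata4/6 or Gata6, passed under edgeR (−0.272 and −0.248) and DESeq2 (−0.245 and −0.259). The cause was not tested.

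Leaving out a replicate kept 39 of 40 gene counts, 281 of 284 list means and 570 of 576 named values. The Irf1 count was 2573 without shIrf1 replicate 2 and 2807 without replicate 1, against 3957. Gata6 in Gata4/6 ranged from 0.175 to 0.235 and lost its call each time. Leaving out a library moved chemokines in Irf2 between 0.273 and 0.659, macrophage markers in Gata4/6 between 0.166 and 0.368, Lrat in Gata4/6 between −0.0268 and 0.479, and cell cycle genes in Ets1/2 between −0.0049 and 0.0276. A call also changed for quiescent HSC markers in Ets1 (0.130 to 0.250), macrophage markers in Gata4 (0.189 to 0.304), matrix genes in Irf1 (0.0695 to 0.128) and Cxcl5 in Gata6 (1.40 to 1.77). Where a group was left with a lone library, it was assumed to vary like the other groups.

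Pooling the controls of the same dose kept 3 of 9 gene counts. Ets2 gave 2341, Gata4 3057, Irf1 1582, Irf2 2613, Ets1/2 4245 and Irf1/2 2707. In Ets1, Col1a2 turned to −0.174, collagens to −0.02, hepatocyte markers to −0.0731 and quiescent HSC markers to −0.398. In Gata6, Gata6 itself (−0.0284) and the activation markers (0.176) lost their calls. Cell cycle genes in Ets1/2 turned to −0.405, Gata6 in Gata4/6 fell short at 0.109, and in Irf1/2 Col1a1 turned to 0.036 and collagens to 0.197. Pooling all 7 controls gave counts of 1793 in Irf1, 1032 in Irf2 and 4052 in Ets1/2. Quiescent HSC markers in Ets1 turned to −0.0847, Gata6 in the Gata6 knockdown to 0.0857 and cell cycle genes in Ets1/2 to −0.631. Activation markers in Irf2 (−0.212) and Gata6 in Gata4/6 (0.0234) lost their calls, and Gata4 in Gata4/6 gained one (−0.369). Pooled controls mix groups that differ from each other, which widens their spread, but how far this lowers the counts was not tested.

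Against the other control hairpin, counts moved past 1.5 times in Gata6 (6326), Irf2 (1247) and Ets1/2 (4246). In Ets1, Col1a2 (−0.765), collagens (−0.33), hepatocyte markers (−0.292), macrophage markers (−0.555) and quiescent HSC markers (−0.692) turned, and activation markers lost their call (0.101). In Ets2, Col3a1 (−0.0171) and macrophage markers (−0.0413) turned. In Gata4, cell cycle genes (−0.17) and macrophage markers (−0.4) turned. In Gata6, Gata6 itself (0.18) and collagens (−0.0839) turned, and activation markers lost their call (0.0665). In Irf1, Ptgs2 (−0.792), Mki67 (0.553) and cell cycle genes (0.339) turned. In Irf2, Mki67 (0.0439), Acta2 (−0.0918), cell cycle genes (0.0367) and interferon-stimulated genes (0.241) turned. In Ets1/2, Ets1 (0.212) and cell cycle genes (−0.822) turned. In Gata4/6, Col1a2 (−0.281), Lrat (−0.941), matrix genes (−0.0106), hepatocyte markers (−0.279) and interferon-stimulated genes (−0.0852) turned, Gata6 lost its call (0.013) and Gata4 gained one (−0.345). In Irf1/2, Mx1 (0.37), Col1a1 (0.641), Col1a2 (0.894), activation markers (0.503), interferon-gamma-induced genes (0.214), collagens (0.763) and macrophage markers (0.106) turned. The difference between the control hairpins enters these values by construction, and its cause was not tested.

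Peak overlaps moved with the overlap rule. The share of quiescent H3K4me2 peaks overlapped in activated HSCs was 63.3% and became 62.8% at 50% of the shorter peak, 65.7% with peaks widened by 500 bp, 86.6% for the longer peaks alone and 72.7% for an equal number of the longest peaks. Under the same 4 rules, lost H3K4me2 peaks at 1 month went from 33.9% to 32.6%, 37.1%, 63.8% and 45.7%. Gained H3K4me2 peaks went from 19.2% to 20.5% when widened, 42.8% for the longer peaks and 28.8% at equal number. Quiescent H3K27ac peaks overlapped in activated HSCs went from 76.2% to 73.2%, 81.6%, 91.1% and 57.9%. Lost H3K27ac peaks at 1 month went from 17.8% to 21.2% when widened, 27.8% for the longer peaks and 26.2% at equal number. Gained H3K27ac peaks went from 34.0% to 31.9%, 39.4%, 53.5% and 35.8%. Human H3K4me2 went from 82.6% to 81.1%, 85.3%, 97.1% and 79.6%, and human H3K27ac from 79.4% to 78.7%, 80.9%, 95.6% and 77.6%. The share of H3K4me2 peaks with H3K27ac, at 50% of the shorter peak, widened and for longer peaks, went from 24.6% to 23.8%, 26.7% and 42.8% in quiescent HSCs and from 61.1% to 59.5%, 63.6% and 79.9% in activated HSCs. At 1 week it went from 58.7% to 56.6%, 62.2% and 81.5%, and at 1 month from 48.9% to 46.7%, 53.4% and 72.1%. In human source 1 it went from 63.5% to 59.8%, 66.4% and 83.7%, and in source 2 from 56.8% to 55%, 59.5% and 78.7%. Longer peaks overlap more by construction. All 16 gene counts near peaks stayed within their 95% binomial interval at 1000 bp.

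No paired analysis was possible because the RNA labels carry no number that joins a knockdown library to a control library, and no test compares the marks whose human sources are shared. Score thresholds on peaks were not run because the files hold no score. Depth limits what is called: with 12853227 reads in the smallest library, genes of a few reads were not tested, and folds of 1.5 were found in 77.6% of simulated genes where the control had 1 library.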

Other observations

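Libraries with 1 and 2 control vectors differed, with no gene targeted. With SHC202, 3740 genes differed between 2 vectors and 1. Contractile genes were higher with 2 vectors at 12 of 17 (mean log2 0.48), while cell cycle genes were lower at 29 of 35 (mean log2 −0.46) and macrophage markers at 12 of 17 (mean log2 −0.49). With SHC002, 2664 genes differed, contractile genes were lower at 13 of 17 (mean log2 −0.39) and hepatocyte markers at 9 of 12 (mean log2 −1.63). The change with dose differed between the hairpins by −0.88 in the mean of the contractile genes and by −1.12 in that of the hepatocyte markers.

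Only 3 lymphocyte genes passed the filter on low values, too few for a test. Their mean log2 change was −0.41 in Ets1/2, 0.47 in Gata4/6 and 0.03 in Irf1/2.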
